A study of Mus musculus with 6 samples.

How the data were processed

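RNA of single mouse embryonic stem cells was counted with SORT-seq, a plate-based form of CEL-Seq2 that counts the 3' ends of transcripts with molecular identifiers (UMIs). R1 and IB10 are established mouse embryonic stem cell lines, and each gave 1 library in each of 3 conditions, so the comparisons rest on 6 libraries. LIF_2i cells were kept with LIF, 3 µM CHIR99021 (an inhibitor of GSK3, which activates WNT signalling) and 0.1 µM PD325901 (an inhibitor of MEK). Rosette_LIM cells were kept with LIF, 2 µM IWP2 (an inhibitor of WNT secretion) and 0.1 µM PD325901, for 6 passages in R1 and 5 passages in IB10. Primed_4d cells were grown for 4 days with LIF, 12 ng/ml FGF2, 20 ng/ml Activin A and 2 µM IWP2. Passage numbers at collection differed with the condition: 24 for R1 and 28 for IB10 in LIF_2i and primed_4d, and 28 and 33 in rosette_LIM. Per the labels' protocols, cells were dissociated with trypsin, sorted by FACS into 384-well plates that held ERCC spike-in RNA, lysed by heat, and sequenced on a NextSeq 500. The labels state 192 wells per sample, of which 4 were left empty, and 188 wells per library were used here. Which libraries shared a plate is not given in the sources used here.

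The deposited table holds an expected count per gene and well, which the authors made from the UMIs; the submitters' processing notes name BWA and the mm10/GRCm38 build. Software versions and the gene annotation used for counting are not given in the sources used here. All 1297 distinct values in the table equal, to 2 decimals, the number of molecules expected from a whole number of the 4096 UMIs that 6 bases allow, and the totals differ from well to well. The deposited values are therefore UMI counts corrected for molecules that drew the same UMI, with no scaling to a common depth. The correction added between 1.32% and 2.57% to the total of a library. The table has 19623 rows, of which 91 are ERCC spike-ins and 19532 are genes; 1470 gene rows were 0 in every well. All 1128 columns were used. ERCC rows took 1.76% of all counts and were kept out of library sizes and tests. Coordinates are GRCm38 positions from a GENCODE M21 annotation, matched by symbol for 18222 gene rows and for 226 of the 239 genes named by rule.

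Cells of a library are not replicates, so the values were summed over the wells of each library and rounded to whole numbers. The plan fixed before the data were examined gave edgeR's quasi-likelihood test for raw counts and limma for normalized values; since the values proved to be counts, edgeR took the main place and limma on log2(ppm + 5) became an alternative. edgeR 4.0.16 in R 4.3.3 used TMM factors, filterByExpr with a minimum count of 10, and a model of condition and cell line over all 6 libraries, which share 1 estimate of spread (common dispersion 0.0106, a biological coefficient of variation of 0.103). It tested 12098 genes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Cell line is a block because libraries with the same replicate number come from the same line in the labels; the IB10 minus R1 differences correlated across genes by 0.181 between LIF_2i and rosette_LIM, 0.259 between LIF_2i and primed_4d, and 0.109 between rosette_LIM and primed_4d. Nothing in the labels says that separate cultures were made within a line, so p-values measure the spread between these libraries. With groups of 2, the smallest p of an exact permutation test is 0.333, so no such test was run. Log2 fold changes are ± a standard error derived from edgeR's test. Levels are CPM (counts scaled by library size), mean ± SD of 2 libraries. With no UMI in a group the fold is a lower bound against 3 counts over the group. With 1 to 3 UMIs it is a ratio with an exact 95% interval. Intervals and bounds cover counting error only.

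Gene lists (25, with 342 genes, of which 338 were found) were also fixed in advance: naive pluripotency, formative and primed pluripotency, core pluripotency, WNT/beta-catenin targets, FGF/ERK targets, Nodal/Activin targets, LIF/STAT3 targets, DNA methylation machinery, methylation-sensitive germline genes, epithelial polarity and lumen formation, basement membrane and integrins, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, S phase, G2/M phase, p53 targets, dissociation and heat stress, 2-cell-like, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm and feeder fibroblast genes. Some genes stand in more than 1 list (such as Tfcp2l1, Klf4, Etv4, Col4a1 and Esrrb). Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data. The latter setting also takes only the few residual degrees of freedom of 6 libraries, which by itself raises p. In primed_4d against LIF_2i the formative and primed list had an estimated correlation of −0.0259, under the preset. Its unadjusted camera p still moved from 2.13e-22 to 0.00831. Calls lost in that setting therefore do not show that correlation between genes made them. The genes named are, for each condition comparison, the 10 with the largest rise and the 10 with the largest fall among those past the threshold with the same direction in both lines, 5 on each side for IB10 against R1, up to 4 members of each list with the largest absolute change, and Xist, Otx2, Pou5f1, Sox2, Klf4, Esrrb and Fgf5. Spike-ins, Gm-numbered and Rik-named genes, mitochondrial genes and pseudogenes named with -ps were left out of the ranked part. Some genes that the rule or a list names are not reported here. Folds of Zscan4, Usp17l, Tuba3, Pramel7, Igll1 and Vpreb1 are uncertain, since these genes have near-identical copies between which reads can be split.

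For single cells, wells of 6000 UMIs or more were kept (946 of 1128). Shares of cells and list scores used cells thinned to 10000 UMIs, leaving out shallower cells; a score is the mean over a list of log2(1 + UMIs). Cells were clustered with scanpy 1.11.5 (Leiden, leidenalg 0.10.2, resolution 1, 20 principal components, seed 1), and named only by marker genes fixed in advance. No doublet caller was run: each well received a sorted cell, and both wells above 200000 UMIs are given with their values. Along a chromosome, the share of each cell's UMIs was set against the mean of the 6 libraries on a log2 scale, in cells of 10000 UMIs or more. The 6000 and 200000 UMI limits and the thresholds on chromosomes 8 (0) and 6 (0.25) were set after the distributions were seen. Rn45s and mitochondrial genes were left out of the chromosome shares, also after a first look in which they spread the values of chromosome 17.

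On simulated counts with the means and sizes of these libraries, edgeR recovered 61% of genes changed by a log2 of 1 and 89% of those changed by a log2 of 2 in rosette_LIM against LIF_2i (100 genes of each size, 11786 genes tested), with 5.06% of its calls false. limma 3.58.1 recovered 56% and 81% (8476 genes), and DESeq2 1.42.0 recovered 39% and 80%. For comparisons that share the LIF_2i libraries, 20 simulations with no change gave the values that chance allows. The alternatives tried were limma with pseudocounts of 5, 1 and 20 ppm, other abundance filters, no rescaling of the libraries, library totals without TMM, DESeq2's size factors within edgeR (RLE), DESeq2, no replicate block, wells within 3-fold of their library's median, each library left out in turn, wells of 6000 UMIs or more, leaving out the largest wells, UMIs before the correction, limma with equal weight per cell, and chromosome 8 genes or classes of cells left out. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.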

Results

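Transcripts were counted in single mouse embryonic stem cells of the lines R1 and IB10 under 3 culture conditions, with 188 wells per library and 2 libraries per condition (1 per line). LIF_2i is the naive culture with WNT signalling activated and MEK inhibited. Rosette_LIM is the culture, named for the rosette stage of the early epiblast, in which MEK stays inhibited and WNT secretion is blocked. Primed_4d cells had 4 days of FGF2 and Activin A with WNT secretion blocked. The libraries held 6696251 (R1) and 7688723 (IB10) UMIs in LIF_2i, 5748432 and 5093785 in rosette_LIM, and 4614580 and 5221351 in primed_4d. The median well had 32639 and 40976 UMIs in LIF_2i, 31055 and 26868 in rosette_LIM, and 11250 and 27257 in primed_4d. Of the R1 primed_4d wells, 84 of 188 held under 6000 UMIs, against 4 to 38 wells in the other libraries. A pair of R1 LIF_2i wells held 324128 and 523372 UMIs, which was 4.84% and 7.82% of that library. Across genes, which are not independent replicates, log2 levels of the lines correlated within a condition by 0.995 in LIF_2i, 0.993 in rosette_LIM and 0.992 in primed_4d. Rosette_LIM and LIF_2i libraries correlated by 0.987 to 0.991, and primed_4d libraries with all others by 0.959 to 0.966.

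Rosette_LIM was compared with LIF_2i: WNT activation gives way to a block of WNT secretion, MEK stays inhibited and passage is higher. Sp5, a transcription factor that is a direct target of the pathway, was 15.6-fold lower (log2 −3.96 ± 0.32, edgeR adjusted p = 5.73e-06, n = 2 libraries per group). It was at 29.2 ± 9.52 CPM in LIF_2i and 1.84 ± 0.11 CPM in rosette_LIM. The caudal homeobox gene Cdx1 was 10.7-fold lower (−3.41 ± 0.28, edgeR adjusted p = 6.06e-06). Axin2, a feedback inhibitor of the pathway, fell by 2.39 ± 0.28 (edgeR adjusted p = 0.000134), from 29.6 to 5.46 CPM. Otx2, a transcription factor of the exit from naive pluripotency, was 5.18-fold higher (2.37 ± 0.30, edgeR adjusted p = 0.000266). Its level was 2.78 ± 1.51 CPM in LIF_2i, 14.3 ± 1.30 CPM in rosette_LIM and 16.1 ± 3.17 CPM in primed_4d. The naive factors Klf4 (−0.36 ± 0.13, edgeR adjusted p = 0.143) and Esrrb (−0.29 ± 0.11, edgeR adjusted p = 0.143) did not pass the test. They were at 217 ± 23.9 and 369 ± 40.0 CPM in rosette_LIM. The core factors Pou5f1 (−0.17 ± 0.11, edgeR adjusted p = 0.439) and Sox2 (0.33 ± 0.11, edgeR adjusted p = 0.119) did not pass. Nor did the primed marker Fgf5 (1.33 ± 0.86, edgeR adjusted p = 0.441) and Xist, the RNA of X inactivation (0.39 ± 0.46, edgeR adjusted p = 0.705). On GRCm38, Sp5 lies on chromosome 2 from 70474923 to 70477729 and Cdx1 on chromosome 18 from 61018862 to 61036199. Axin2 lies on chromosome 11 from 108920349 to 108950783 and Otx2 on chromosome 14 from 48657677 to 48673819.

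Among the 10 largest rises in rosette_LIM was the FGF receptor Fgfr2, from 1.14 ± 0.39 to 13.0 ± 6.26 CPM (3.47 ± 0.35, edgeR adjusted p = 3.43e-05). The retinoic acid binding protein Crabp2 rose from 3.53 ± 1.35 to 30.1 ± 6.36 CPM (3.07 ± 0.28, edgeR adjusted p = 1.35e-05). Hesx1, a homeobox gene of the anterior epiblast and forebrain, rose by 3.70 ± 0.62 (edgeR adjusted p = 0.00261) to 5.47 CPM and was at 0.712 CPM in primed_4d. Gadd45g rose by 3.36 ± 0.36 and the Notch ligand Dll1 by 2.98 ± 0.60 (edgeR adjusted p of 5.45e-05 and 0.00942). Bcl11a rose by 2.94 ± 0.53, Lrtm2 by 3.49 ± 0.64 and Myl9 by 3.74 ± 0.99 (edgeR adjusted p of 0.00412, 0.0049 and 0.0391). The neuroendocrine transcription factor Insm1 had 25 UMIs in rosette_LIM and 1 in LIF_2i, a ratio of 34 (95% counting interval 5.57 to 1400, edgeR adjusted p = 0.0103). The histone deacetylase Hdac9 had 26 and 3, a ratio of 11.8 (3.61 to 60.9, edgeR adjusted p = 0.015). Beside Sp5 and Cdx1, T (brachyury), a mesoderm gene and WNT target, fell by 3.37 ± 0.67 (edgeR adjusted p = 0.00805). The neurofilament gene Nefm fell by 3.91 ± 0.36, Pglyrp1 by 3.85 ± 0.32 and Bach2 by 3.59 ± 0.46 (edgeR adjusted p of 1.58e-05, 8.23e-06 and 0.000313). Mfsd7c fell by 3.38 ± 0.52, Sh2d4b by 3.33 ± 0.73 and the guidance cue Ntn1 by 2.96 ± 0.29 (edgeR adjusted p of 0.00153, 0.0161 and 3.02e-05). Cnga4 had 59 UMIs in LIF_2i and 2 in rosette_LIM, a ratio of 21.7 (5.74 to 183, edgeR adjusted p = 0.00363). Fgfr2 lies on chromosome 7 from 130162451 to 133123350, Crabp2 on chromosome 3 from 87948666 to 87953376, and Hesx1 on chromosome 14 from 26994416 to 27002329 (GRCm38).

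**Figure D1:**
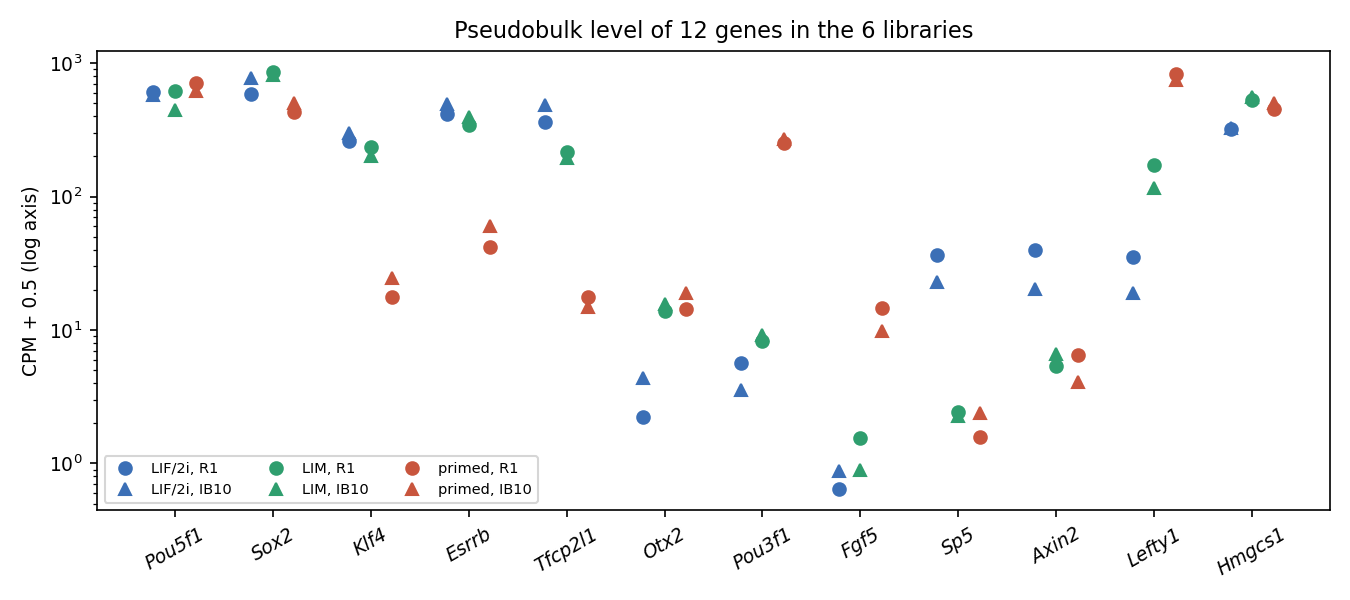
Levels of 12 genes in the 6 libraries (CPM + 0.5, log axis), with 1 point per library and lines marked apart. Sp5 and Axin2 are lower and Otx2 is higher in both rosette_LIM libraries than in both LIF_2i libraries, while Klf4 and Esrrb are at 279 and 453 CPM in LIF_2i and 217 and 369 CPM in rosette_LIM and fall to 20.5 and 50.7 CPM in primed_4d.

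Camera called 9 of the 25 lists in rosette_LIM against LIF_2i. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05, and fry called 0, with 7. Of 14 WNT/beta-catenin targets 6 fell and 1 rose, the same counts as adjusted over the list alone. For the WNT list camera's adjusted p was 3.42e-10 (adjusted p = 0.387 with an estimated correlation). Beside the genes above, Bmp4 (−1.57) and Tnfrsf19 (−0.85) fell and the receptor Lgr4 (0.67) rose. Of 14 cholesterol synthesis genes 11 rose, and 12 when adjusted over the list alone. For the cholesterol list camera's adjusted p was 2.88e-16 (adjusted p = 0.387 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, rose from 322 to 544 CPM (0.76 ± 0.10, edgeR adjusted p = 0.000456). Sc4mol (0.86 ± 0.12), Fdps (0.83 ± 0.11) and Lss (0.81 ± 0.12) rose with edgeR adjusted p of 0.000538, 0.000538 and 0.00102. Of 5 neuroectoderm genes the eye and neural factor Pax6 rose from 2.28 to 12.4 CPM (2.42 ± 0.33, edgeR adjusted p = 0.000546). The neuronal tubulin Tubb3 rose from 66.9 to 157 CPM (1.21 ± 0.14, edgeR adjusted p = 0.000125), while Nes (1.14 ± 0.32) and Map2 (0.89 ± 0.55) did not pass. For the neuroectoderm list 4 members rose when adjusted over the list alone, and camera's adjusted p was 1.89e-07 (adjusted p = 0.387 with an estimated correlation). Of 13 Nodal/Activin targets 2 rose and 1 fell (3 and 1 adjusted over the list alone). The Nodal antagonist Lefty1 was 5.45-fold higher (2.45 ± 0.16, edgeR adjusted p = 2.8e-06), from 26.7 to 144 CPM. The inhibitory Smad7 fell by 0.70 ± 0.13 (edgeR adjusted p = 0.00669), and Skil was at 0.57 ± 0.17. For the Nodal list camera's adjusted p was 0.0313 (adjusted p = 0.387 with an estimated correlation), and its median of 0.09 turned to −0.34 with no rescaling of the libraries.

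Of 5 primitive endoderm genes 1 rose, the same adjusted over the list alone: the basement membrane collagen Col4a1, from 8.34 to 34.5 CPM (2.05 ± 0.20, edgeR adjusted p = 2.3e-05). Lama1 (0.49), Sparc (0.41) and Gata4 (0.32) did not pass. For primitive endoderm camera's adjusted p was 0.00259 (0.454 with an estimated correlation), and the no-rescaling shift turned its median of 0.41 to −0.04. Of 13 basement membrane and integrin genes Col4a1 and Col4a2 (1.65 ± 0.34, edgeR adjusted p = 0.0106) rose, and Lamb1 (0.92) and Itga6 (0.50) did not pass (5 up and 1 down adjusted over the list alone). For basement membrane camera's adjusted p was 0.0313 (0.387 with an estimated correlation), and the no-rescaling shift turned its median of 0.03 to −0.40. Of 16 G2/M genes Ccnb2 (0.50 ± 0.11), Hmmr (0.42 ± 0.11) and Cdk1 (0.37 ± 0.10) rose (edgeR adjusted p of 0.0174, 0.0438 and 0.0452), though Hmmr turned to −0.02 and Cdk1 to −0.07 with no rescaling. Bub1 (0.41, edgeR adjusted p = 0.0597) did not pass, and 8 members rose when adjusted over the list alone. For G2/M camera's adjusted p was 8.80e-05 (0.387 with an estimated correlation), and the no-rescaling shift turned its median of 0.27 to −0.17. Of 16 nuclear oxidative phosphorylation genes Sdhb (0.50 ± 0.12) and Atp5b (0.41 ± 0.10) rose (edgeR adjusted p of 0.0222 and 0.0241), though Atp5b turned to −0.03 with no rescaling. Cox7c (0.45) and Ndufa1 (0.33) did not pass, and 4 members rose when adjusted over the list alone. For oxidative phosphorylation camera's adjusted p was 0.0264 (0.387 with an estimated correlation), and the no-rescaling shift turned its median of 0.17 to −0.27. Of 18 FGF/ERK targets 3 fell, and 5 when adjusted over the list alone. For the ERK list camera's adjusted p was 0.0181 (adjusted p = 0.433 with an estimated correlation). The ETS factor Etv4 fell from 113 to 39.0 CPM (−1.53 ± 0.18, edgeR adjusted p = 0.000134), and Spry2 (−0.68) and Spred1 (−0.68), whose products dampen receptor signalling, fell too. Spry4 (−1.06), Egr1 (1.23) and Ier3 (0.92) did not pass.

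The lists that name the pluripotent states were not called. Of 22 naive genes 2 rose and 3 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.341). The lysosomal Manba fell by 1.36 ± 0.32, threonine dehydrogenase Tdh from 624 to 258 CPM (−1.29 ± 0.12) and the naive factor Tfcp2l1 from 425 to 204 CPM (−1.05 ± 0.14), with edgeR adjusted p of 0.0203, 1.89e-05 and 0.000383. Fgf4 (0.74 ± 0.13, edgeR adjusted p = 0.00369) and Fbxo15 (0.63) rose. Of 26 formative and primed genes 5 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.0537). Otx2, Pou3f1 (1.01), Gng3 (0.96), Sfrp2 (0.80) and the DNA methyltransferase Dnmt3a (0.72 ± 0.13) rose, and Etv4 and the DNA methyltransferase Dnmt3b (−0.92 ± 0.16) fell. Zic5 (1.89 ± 0.73) did not pass. Of 10 genes of the DNA methylation machinery Dnmt3a rose, and Dnmt3b and Uhrf1 (−0.45 ± 0.11) fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.805). Of 13 LIF/STAT3 targets Tfcp2l1 fell (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.734), and Junb was at 0.60, Socs3 at 0.59 and Pim3 at 0.43. Of 19 epithelial polarity and lumen genes the sialomucin Podxl, found on lumen surfaces, rose (1.00 ± 0.28, edgeR adjusted p = 0.0477). The tight junction gene Cldn3 fell by 1.85 ± 0.41 (edgeR adjusted p = 0.0163), and Cldn4 (−0.53) and Prkcz (−0.49) did not pass (1 and 3 adjusted over the list alone, camera adjusted p = 0.734).

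Of 12 p53 targets Mdm2 (0.46 ± 0.12) rose and the cell cycle inhibitor Cdkn1a (−1.11 ± 0.21) fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.785). Of 6 trophectoderm genes Tfap2c (0.62 ± 0.16) rose (1 and 2 adjusted over the list alone, camera adjusted p = 0.785), with a median of 0.06, a mean of −0.15 and a test pointing down. Of 5 mesendoderm genes T fell (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.0802). In 8 lists edgeR called 0 members, and DESeq2, limma and adjustment over the list alone called 0 as well. These were core pluripotency (12 genes, 3 at an unadjusted p under 0.05, camera adjusted p = 0.775), with Lin28a at −0.55, Tdgf1 at 0.23 and Sall4 at 0.20, S phase (15 genes, 5 unadjusted, 0.734) and the mitochondrially encoded genes (12, 3 unadjusted, 0.734). They also were the germline (14 genes, 2 unadjusted, 0.496), glycolysis (14, 1 unadjusted, 0.782), stress (12, 1 unadjusted, 0.737), feeder fibroblast (5, 1 unadjusted, 0.734) and 2-cell-like lists (4, 1 unadjusted, 0.734).

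Over all 12098 genes tested, edgeR called 386 higher and 284 lower in rosette_LIM than in LIF_2i (5.54% of genes), 191 and 120 of them by 2-fold or more. Each LIF_2i library weighed on these counts: 28 rose and 35 fell without R1 LIF_2i, and 88 and 61 without IB10 LIF_2i. Of the genes named by rule, Sp5, Cdx1, Otx2, Lefty1, Col4a1, Fgfr2, Crabp2, Gadd45g, Bach2, Nefm, Ntn1, Pglyrp1, Etv4 and Tdh were called whichever 1 library was left out. The calls for Pax6, Axin2, Tubb3, Hmgcs1, Sc4mol, Fdps, Cdkn1a, Bcl11a and Mfsd7c were lost without R1 LIF_2i, those for Tfcp2l1 and Fgf4 without IB10 LIF_2i, and the remaining ones without R1 LIF_2i and again without IB10 LIF_2i. DESeq2 called 170 and 109, and edgeR with no replicate block 162 and 119. With DESeq2 the calls for Insm1, Uhrf1, Cldn3, Podxl, Hmmr, Cdk1, Manba, Sdhb, Cdkn1a, Mdm2 and Tfap2c were lost, and DESeq2 gave no adjusted p for Hesx1, Myl9, Lrtm2, Hdac9, Cnga4, Sh2d4b and T. With no rescaling of the libraries the median of all genes moved to −0.44 and the calls to 149 and 3083, so that 4.6% rather than 57.6% of calls were rises. Spry2, Spred1, Bmp4, Tnfrsf19, Lgr4, Fbxo15, Pou3f1, Gng3 and Sfrp2 were chosen here after their values were seen.

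**Figure D2:**
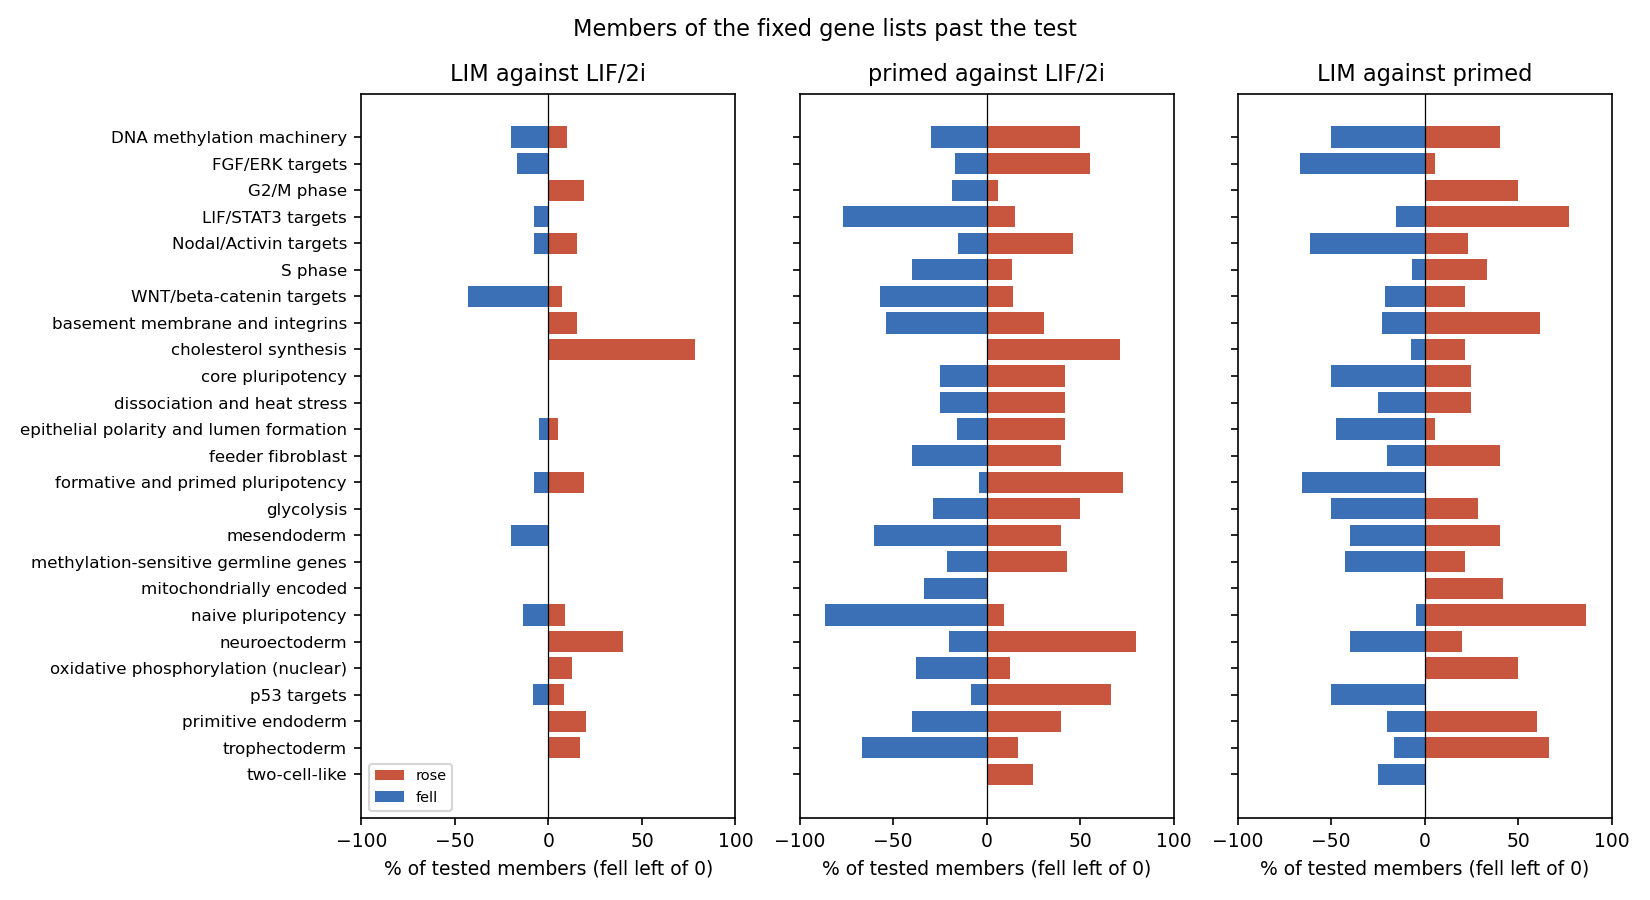
Percent of tested members of each of the 25 gene lists that passed edgeR's test, with rises to the right and falls to the left, for the 3 condition comparisons with 2 libraries per group. In rosette_LIM against LIF_2i the cholesterol synthesis list has 11 of 14 members up, and in primed_4d against LIF_2i the naive list has 19 of 22 down and the formative and primed list 19 of 26 up; with no rescaling the median of all genes is −0.44 and −0.58 in these comparisons, and the cholesterol list's median in primed_4d turns from 0.56 to −0.01.

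Primed_4d was compared with LIF_2i to measure the exit from the naive state over 4 days. Naive genes were lower: Tfcp2l1 was 26.9-fold lower (log2 −4.75 ± 0.18, edgeR adjusted p = 1.49e-10, n = 2 libraries per group) and Klf4 13.6-fold lower (−3.76 ± 0.16, edgeR adjusted p = 6.91e-10). Esrrb was 8.98-fold lower (−3.17 ± 0.13, edgeR adjusted p = 3e-10), and Tbx3, another naive factor, fell by 4.29 ± 0.19 (edgeR adjusted p = 8.15e-10) from 198 to 10.3 CPM. Primed genes were higher: the POU factor Pou3f1 was 63.5-fold higher (5.99 ± 0.19, edgeR adjusted p = 5.46e-11), at 4.11 CPM in LIF_2i and 260 CPM in primed_4d. The growth factor Fgf5 was 39.4-fold (5.30 ± 0.55, edgeR adjusted p = 3.49e-06) and the de novo methyltransferase Dnmt3b 10.3-fold higher (3.36 ± 0.16, edgeR adjusted p = 1.4e-09). Otx2 was 5.78-fold higher (2.53 ± 0.30, edgeR adjusted p = 1.06e-05). Sox2 fell by 0.53 ± 0.12 (edgeR adjusted p = 0.00214), Xist rose by 1.46 ± 0.42 (edgeR adjusted p = 0.0135), and Pou5f1 did not pass (0.16 ± 0.11, edgeR adjusted p = 0.271). The calls for Sox2 and Xist were lost without IB10 LIF_2i, and that for Xist also without IB10 primed_4d and with DESeq2. Klf4 lies on chromosome 4 from 55527143 to 55532466, Esrrb on chromosome 12 from 86361117 to 86521628, and Tfcp2l1 on chromosome 1 from 118627945 to 118685168. Pou3f1 lies on chromosome 4 from 124656807 to 124660655, Fgf5 on chromosome 5 from 98254184 to 98277030, and Dnmt3b on chromosome 2 from 153649450 to 153687730 (GRCm38).

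The 10 largest rises held genes with no UMI in LIF_2i, whose folds are bounds against 3 counts over the group. The carbonic anhydrase Car4 was at least 87.7-fold higher (177 UMIs in primed_4d), Zfp608 at least 79.3-fold and the protocadherin Pcdh8 at least 48.5-fold. The homeobox genes Hoxb1 and Hoxb5 were at least 46.1-fold and 21.8-fold higher, the retinoid receptor Rxrg at least 39.1-fold and the GABA receptor subunit Gabra4 at least 24.8-fold. Gbp2 was at least 21.8-fold and Car14 at least 21.3-fold higher. Tmem54 had 261 UMIs and 1, a ratio of 388 (69 to 15400, edgeR adjusted p = 4.96e-08). The 10 largest falls had no UMI in primed_4d. Cryge was at least 16.2-fold lower, Gpr126 at least 15.9-fold, Sh2d4b at least 15.7-fold and the fatty acid receptor Ffar3 at least 10.8-fold. Pramel7 and Msln were at least 9.87-fold lower, the thyroid hormone receptor Thrb at least 6.73-fold, Vpreb1 at least 6.28-fold and the matrilin Matn1 at least 4.71-fold. With DESeq2 the calls for Hoxb1, Hoxb5, Gbp2, Car14 and Sh2d4b were lost. Car4 lies on chromosome 11 from 84957786 to 84966044 and Hoxb1 on the same chromosome from 96365752 to 96368256 (GRCm38).

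Camera called 13 of the 25 lists in primed_4d against LIF_2i. With an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05, and fry called 12. Counts adjusted over the list alone were the same as over all genes unless given. Of 22 naive genes 19 fell and 2 rose, Dppa3 (0.94) and Gbx2 (0.79), the same adjusted over the list alone. For naive genes camera's adjusted p was 1.4e-34 (adjusted p = 0.168 with an estimated correlation). Prdm14, a repressor of methylation and FGF signalling in naive cells, fell by 3.53 ± 0.28 (edgeR adjusted p = 2.43e-07). Of 26 formative and primed genes 19 rose and Etv4 (−0.56) fell, the same adjusted over the list alone. For formative genes camera's adjusted p was 2.67e-21 (adjusted p = 0.168 with an estimated correlation). Fgf15 rose from 0.486 to 40.3 CPM (6.33 ± 0.41, edgeR adjusted p = 3.23e-08). Of 18 FGF/ERK targets 10 rose and 3 fell. For ERK targets camera's adjusted p was 8.08e-06 (adjusted p = 0.307 with an estimated correlation). The immediate early gene Egr1 (6.11 ± 0.50, edgeR adjusted p = 3.3e-07), the ERK phosphatases Dusp4 (3.99 ± 0.32) and Dusp6 (2.28 ± 0.22) and Spry4 (1.65 ± 0.24) rose. Etv4, Etv5 (−0.67) and Phlda1 (−1.05) fell. Of 13 Nodal/Activin targets 6 rose and 2 fell (7 and 3 adjusted over the list alone). For Nodal targets camera's adjusted p was 8.81e-08 (adjusted p = 0.222 with an estimated correlation). Lefty1 (4.94 ± 0.17), Skil (2.45 ± 0.16) and Fgf8 (2.44 ± 0.65) rose, and Fst (−1.20) and Pmepa1 (−0.43) fell. Of 13 LIF/STAT3 targets 10 fell and 2 rose, Junb (1.46) and Gbx2. For STAT3 targets camera's adjusted p was 8.81e-08 (adjusted p = 0.222 with an estimated correlation). Ccnd3 (−2.24 ± 0.21) and Bcl3 (−1.98 ± 0.18) fell beside Tfcp2l1 and Klf4. Dppa3, Gbx2, Etv5, Phlda1, Fst and Pmepa1 were chosen after their values were seen.

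Of 19 epithelial polarity genes 8 rose and 3 fell. For polarity genes camera's adjusted p was 0.00137 (0.307 with an estimated correlation). The median of 0.22 turned to −0.36 with no rescaling, which shifts all genes (median −0.58). The tight junction claudins Cldn6 (4.23 ± 0.26) and Cldn7 (3.93 ± 0.26), the apical Crb3 (2.80 ± 0.40) and Podxl (2.36 ± 0.25) rose. Of 13 basement membrane genes 7 fell and 4 rose. For membrane genes camera's adjusted p was 0.0380 (adjusted p = 0.352 with an estimated correlation). Nidogen Nid1 (−3.48 ± 0.18), Lama1 (−1.83 ± 0.36) and Sparc (−1.73 ± 0.17) fell and Lamb1 (1.83 ± 0.26) rose. Of 12 core pluripotency genes 5 rose and 3 fell. For core genes camera's adjusted p was 0.0127 (0.307 with an estimated correlation), and the no-rescaling shift turned their median of 0.16 to −0.42. Lin28a (2.17 ± 0.19), Utf1 (1.68 ± 0.11), Tdgf1 (1.22 ± 0.11) and Dppa4 (0.71 ± 0.11) rose. Of 14 WNT/beta-catenin targets 8 fell and 2 rose (8 and 3 adjusted over the list alone). For WNT targets camera's adjusted p was 0.0162 (adjusted p = 0.466 with an estimated correlation). Cdx1 (−5.57 ± 0.37), Sp5 (−4.22 ± 0.34) and T (−2.91 ± 0.64) fell, and Lef1 (4.14 ± 0.45), a partner of beta-catenin, rose. Of 14 cholesterol genes 10 rose. For cholesterol genes camera's adjusted p was 0.000321 (0.307 with an estimated correlation), and the no-rescaling shift turned their median of 0.56 to −0.01. Lss (1.27 ± 0.12), Fdps (1.10 ± 0.11), Cyp51 (0.69) and Sc4mol (0.69) rose. Of 12 p53 targets 8 rose and Cdkn1a (−0.65) fell. For p53 targets camera's adjusted p was 0.00225 (adjusted p = 0.466 with an estimated correlation). The apoptosis genes Pmaip1 (3.19 ± 0.34) and Bbc3 (1.85 ± 0.17), Eda2r (0.90) and Mdm2 (0.69) rose. Of 5 neuroectoderm genes Pax6 (2.69 ± 0.33), Map2 (2.10 ± 0.49), Sox1 (2.07 ± 0.27) and Nes (2.02 ± 0.30) rose and Tubb3 (−0.74) fell. For neuroectoderm genes camera's adjusted p was 0.0220 (adjusted p = 0.466 with an estimated correlation). Of 16 nuclear oxidative phosphorylation genes 6 fell and 2 rose, with a median of −0.09 and a mean of −0.32, to which the naive factor Esrrb (−3.17), a member of the list, added most. For these genes camera's adjusted p was 0.0411 (adjusted p = 0.352 with an estimated correlation). Cox5a (−0.87 ± 0.10) and Atp5g1 (−0.80 ± 0.10) fell, and Ndufa1 (0.46 ± 0.11) rose but turned to −0.11 with no rescaling.

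The other 12 lists were not called. Of 10 genes of the methylation machinery 5 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.20), with Dnmt3b and Dnmt3a (2.56 ± 0.13) up and the demethylating Tet2 (−1.98 ± 0.21) down. Of 14 germline genes 6 rose and 3 fell (camera adjusted p = 0.20), with Slc25a31 (2.71), Mael (2.60) and Taf7l (2.16) up and Dazl (−2.54) down. The median of that list was −0.04 and the mean 0.35. Of 14 glycolysis genes 7 rose and 4 fell (camera adjusted p = 0.196), with Pfkl (1.80) and the transporter Slc2a1 (1.44) up and Slc2a3 (−1.80) and Hk1 (−1.69) down. Of 6 trophectoderm genes 4 fell and Krt7 (1.64) rose (camera adjusted p = 0.0561), with Gata3 (−2.90), Tead4 (−2.61), Eomes (−1.90) and Tfap2c (−1.90) down. Of 5 mesendoderm genes the WNT ligand Wnt3 (3.90 ± 0.65) and Fgf8 rose and Gsc (−2.91), T and Eomes fell (camera adjusted p = 0.643). Of 5 primitive endoderm genes Dab2 (1.96) and Col4a1 (1.15) rose and Lama1 and Sparc fell (camera adjusted p = 0.662), with a median of 0.72, a mean of 0.05 and a test pointing down. Of 12 stress genes 5 rose and 3 fell (camera adjusted p = 0.139), with Egr1, Hspa1a (2.11 ± 0.68), Jun (1.60 ± 0.40) and Junb (1.46 ± 0.26) up. Of 5 feeder fibroblast genes Tagln (2.45) and Thy1 (1.04) rose and Fn1 (−1.02) and Vim (−0.49) fell (camera adjusted p = 0.580), with a median of −0.49 and a mean of 0.22. Of 16 G2/M genes 1 rose and 3 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.467), and the rise of Bub1 (0.39) turned to −0.18 with no rescaling. Of 15 S phase genes 2 rose and 6 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.125). Of 12 mitochondrially encoded genes 4 fell (camera adjusted p = 0.282), and of 4 genes of the 2-cell-like list Usp17la (2.40) rose (camera adjusted p = 0.413). Krt7 and Vim were chosen after their values were seen.

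edgeR called 2212 genes higher and 2369 lower in primed_4d than in LIF_2i (37.9% of 12098), 1169 and 1159 of them by 2-fold or more. The counts were 1036 and 1281 without R1 LIF_2i, 1184 and 1352 without IB10 LIF_2i, and 1343 and 1432 with DESeq2. With no rescaling the median of all genes moved to −0.58 and the calls to 861 and 6175, so that 12.2% rather than 48.3% of calls were rises. The calls for Sox2, Xist, T, Gata3, Gsc, Bub1, Dab2, Fgf8, Hspa1a, Jun, Map2, Ndufa1, Tagln, Thy1 and Usp17la were lost without 1 or more of the libraries. The 84 R1 primed_4d wells under 6000 UMIs gave 0.545% of their UMIs to naive genes (Wilson 95% interval 0.501 to 0.593), against 0.323% in the deeper wells of that library and 0.766% in the deeper wells of R1 LIF_2i.

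Rosette_LIM was set against primed_4d. Both lack WNT secretion but differ in MEK inhibition, growth factors, treatment time and passage. Klf4 was 10.6-fold (log2 3.40 ± 0.16, edgeR adjusted p = 2.31e-09, n = 2 libraries per group) and Esrrb 7.32-fold higher in rosette_LIM (2.87 ± 0.12, edgeR adjusted p = 1.35e-09). Tfcp2l1 (3.70 ± 0.18, edgeR adjusted p = 2.3e-09) and Tbx3 (4.10 ± 0.19, edgeR adjusted p = 2.05e-09) were also higher. Dnmt3b was 19.4-fold lower in rosette_LIM (−4.28 ± 0.17, edgeR adjusted p = 5.42e-10), at 44.4 CPM against 842 CPM. Pou3f1 (−4.98 ± 0.18, edgeR adjusted p = 2.2e-10) and Fgf5 (−3.98 ± 0.50, edgeR adjusted p = 2.57e-05) were lower. Otx2 did not differ past the test (−0.16 ± 0.25, edgeR adjusted p = 0.657), nor did Xist (−1.08 ± 0.42, edgeR adjusted p = 0.0582). Sox2 was higher (0.86 ± 0.12, edgeR adjusted p = 4.63e-05) and Pou5f1 lower (−0.34 ± 0.11, edgeR adjusted p = 0.0299) in rosette_LIM, and the call for Pou5f1 was lost without IB10 rosette_LIM, without IB10 primed_4d or without either LIF_2i library. Among genes with no UMI in primed_4d the surface glycoprotein Msln was at least 32.1-fold (105 UMIs), Pramel7 at least 16.2-fold, the kallikrein Klk1 at least 14-fold and Matn1 at least 12.5-fold higher in rosette_LIM. Ffar3 (at least 10.1-fold), Thrb (9.77), Fam154a (8.24), AI427809 (7.94) and Igll1 (7.02) followed, also as lower bounds. Among genes with no UMI in rosette_LIM Fndc3c1 was at least 40.8-fold and Hoxb1 at least 33.8-fold lower. The ephrin receptor Epha1 (at least 25.8-fold), Mal2 (22.6), Hoxb5 and Gbp2 (16 each), Car14 (15.7), Ms4a4d (15.3) and Thbs4 (14.2) followed, also as lower bounds. With DESeq2 the calls for Hoxb1, Hoxb5, Gbp2, Car14 and Thbs4 were lost.

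Camera called 11 of the 25 lists between rosette_LIM and primed_4d. With an estimated correlation it called 0, with 5 lists at an unadjusted p under 0.05, and fry called 13. Counts are given as higher and lower in rosette_LIM, and were the same adjusted over the list alone unless given. Of 22 naive genes 19 were higher and Gbx2 (−1.19) lower (19 and 2 adjusted over the list alone), with Prdm14 at 3.80 ± 0.28. For that list camera's adjusted p was 7.1e-35 (adjusted p = 0.159 with an estimated correlation). Of 26 formative and primed genes 17 were lower (18 adjusted over the list alone), with Fgf15 at −4.83 ± 0.37 and Lef1 at −4.75 ± 0.49. Camera's adjusted p for it was 9.2e-18 (adjusted p = 0.159 with an estimated correlation). Of 18 FGF/ERK targets 12 were lower and Etv5 (0.46) higher (12 and 2 adjusted over the list alone). Camera's adjusted p for ERK targets was 4.05e-09 (adjusted p = 0.187 with an estimated correlation). Egr1 (−4.89 ± 0.46), Dusp4 (−4.49 ± 0.36), Spry4 (−2.71 ± 0.28) and the growth regulator Myc (−2.19 ± 0.20) were lower. Of 13 LIF/STAT3 targets 10 were higher, with Ccnd3 at 2.08 and Bcl3 at 1.95, and 2 lower, Gbx2 and Junb. Camera's adjusted p for STAT3 targets was 3.39e-08 (adjusted p = 0.187 with an estimated correlation). Of 13 Nodal/Activin targets 3 were higher and 8 lower (3 and 9 adjusted over the list alone). Camera's adjusted p for Nodal targets was 2.38e-06 (adjusted p = 0.187 with an estimated correlation). Lefty1 (−2.50 ± 0.15), Lefty2 (−2.09 ± 0.16) and Fgf8 (−2.05 ± 0.66) were lower, and the call for Fgf8 was lost without any 1 of the 6 libraries. Of 19 polarity genes 9 were lower and Ezr (0.65) higher. Camera's adjusted p for polarity genes was 0.000279 (adjusted p = 0.187 with an estimated correlation). Cldn7 (−4.16 ± 0.28), Cldn6 (−3.84 ± 0.27), Crb3 (−2.76) and the adhesion molecule Epcam (−2.36 ± 0.21) were lower. Of 13 basement membrane genes 8 were higher, with Nid1 (3.50 ± 0.18), Lama1 (2.32) and Sparc (2.14) leading, and 3 lower. Camera's adjusted p for membrane genes was 0.000696 (adjusted p = 0.187 with an estimated correlation). Ezr, Etv5 and Gbx2 were chosen after their values were seen.

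Nuclear oxidative phosphorylation genes were higher in rosette_LIM for 8 of 16 members, with Cox5a (1.09), Atp5g1 (0.98) and Sdhb (0.61) after the regulator Esrrb. The camera adjusted p was 0.000539 (adjusted p = 0.187 with an estimated correlation). G2/M genes were higher for 8 of 16 members (10 adjusted over the list alone), with Ccnb2 (0.95 ± 0.12), Cdk1 (0.75), Ube2c (0.66) and Aurkb (0.61). For G2/M genes the camera adjusted p was 0.00618 (adjusted p = 0.231 with an estimated correlation). Of 12 p53 targets 6 were lower (7 adjusted over the list alone), with Pmaip1 (−2.48), Bbc3 (−1.74) and Eda2r (−0.59), while Sesn2 (−0.56) did not pass. For p53 genes the camera adjusted p was 0.00242 (adjusted p = 0.473 with an estimated correlation). Of 12 core genes 3 were higher and 6 lower, with Lin28a (−2.72 ± 0.20), Utf1 (−1.51) and Tdgf1 (−0.98) among the latter. For core pluripotency the camera adjusted p was 0.0157 (adjusted p = 0.261 with an estimated correlation). The other 14 lists were not called, and the counts are of higher and lower members. DNA methylation had 4 and 5 of 10 (5 and 5 adjusted over the list alone, camera adjusted p = 0.198), with Tet2 at 1.98 and Dnmt3l at −1.95. Cholesterol synthesis had 3 and 1 of 14 (camera adjusted p = 0.868), with Fdft1 at 0.65, Insig1 at 0.48 and Lss at −0.46. WNT/beta-catenin targets had 3 and 3 of 14 (4 and 4 adjusted over the list alone, camera adjusted p = 0.779), with Notum at 2.21, Cdx1 at 2.15 and Lgr4 at −1.39. Neuroectoderm had 1 and 2 of 5 (1 and 3 adjusted over the list alone, camera adjusted p = 0.956), with Tubb3 at 1.96, a median of −0.88, a mean of −0.32 and a test pointing up. Trophectoderm had 4 and 1 of 6 (camera adjusted p = 0.0732), with Gata3 at 3.11, Tfap2c at 2.52, Tead4 at 1.64 and Krt7 at −1.72. Primitive endoderm had 3 and 1 of 5 (camera adjusted p = 0.0610), with Lama1 and Sparc higher and Dab2 (−2.02) lower. Mitochondrially encoded genes had 5 and 0 of 12 (7 and 0 adjusted over the list alone, camera adjusted p = 0.198), and S phase 5 and 1 of 15 (camera adjusted p = 0.198), with Cdc6 at 0.96 and Rrm2 at 0.74. Stress genes had 3 and 3 of 12 (3 and 4 adjusted over the list alone, camera adjusted p = 0.207), and glycolysis 4 and 7 of 14 (camera adjusted p = 0.232). The 2-cell-like list had 0 and 1 of 4 (camera adjusted p = 0.298), with Usp17la at −3.76. Feeder fibroblast genes had 2 and 1 of 5 (2 and 2 adjusted over the list alone, camera adjusted p = 0.355), with a median of 0.81 and a mean of −0.01. Germline genes had 3 and 6 of 14 (4 and 6 adjusted over the list alone, camera adjusted p = 0.439), with a median of 0.13 and a mean of −0.18. Mesendoderm had 2 and 2 of 5 (camera adjusted p = 0.779), with Wnt3 at 1 UMI in rosette_LIM and 54 in primed_4d, a ratio of 59 with an interval of 10.1 to 2370.

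edgeR called 2299 genes higher and 2073 lower in rosette_LIM than in primed_4d (36.1% of 12098), 1164 and 954 by 2-fold or more. Without R1 primed_4d the counts were 1720 and 1342, and with DESeq2 1479 and 1223. The calls for Aurkb, Cdx1, Dab2, Eda2r, Fgf8, Insig1, Krt7, Lss, Pou5f1, Tead4 and Usp17la were lost without 1 or more of the libraries. With no rescaling the median of all genes was 0.13, and 66.1% rather than 52.6% of calls were higher.

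Changes in rosette_LIM and in primed_4d were set against each other through their shared LIF_2i libraries. Both conditions had 174 rises and 196 falls in common, and 94 genes called in opposite directions. Independent lists give 70.6, 55.6 and 128, and 20 simulations of unchanged groups with the same controls gave means of 0, 0.05 and 0. With no gene changed these means lie near 0 by construction. They cannot show how far shared controls raise the overlap among changed genes. Across genes, which are not independent replicates, the log2 fold changes correlated by 0.34 (0.428 in the simulations). Their covariance was 0.217 against a simulated 0.0508 (0.0477 to 0.0565), a difference of 0.167. With 2 LIF_2i libraries the controls could not be split into parts of 2, and part of the excess in calls may come from sharing them. With the 2 comparisons taken from different lines, so that no LIF_2i library was shared, differences on log2(CPM + 5) correlated by 0.159 (rosette_LIM of R1) and 0.262 (of IB10), against 0.261 within R1 and 0.319 within IB10. Position between the states was measured on genes that differed by a log2 of 1 or more between LIF_2i and primed_4d in the other line. Rosette_LIM lay 8.69% of the way from LIF_2i to primed_4d in R1 (1061 genes) and 16.6% in IB10 (1142 genes). Genes lower in primed_4d gave 6.24% and 15.3%, and genes higher in primed_4d 11.5% and 18.1%. These values carry no test.

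At the level of single cells, rosette_LIM cells had naive scores near those of LIF_2i cells. Over cells thinned to 10000 UMIs the median naive score was 1.36 (R1) and 1.44 (IB10) in LIF_2i, 1.28 and 1.28 in rosette_LIM, and 0.441 and 0.524 in primed_4d. From the 10th to the 90th percentile rosette_LIM cells spanned 1.08 to 1.56 and 1.08 to 1.51. The median formative and primed score was 0.266 and 0.259 in LIF_2i, 0.259 and 0.287 in rosette_LIM, and 0.637 and 0.648 in primed_4d. A rosette_LIM cell scored above a primed_4d cell for naive genes in 98.6% (R1) and 97.3% (IB10) of pairs, and a LIF_2i cell above a rosette_LIM cell in 59.4% and 72.1%. The cells left after thinning were 157 and 184 in LIF_2i, 172 and 147 in rosette_LIM, and 98 and 146 in primed_4d. In R1 primed_4d the shallower 90 wells of 188 thus have no score. These scores compare cells of 1 library per line and condition and carry no test.

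**Figure D3:**
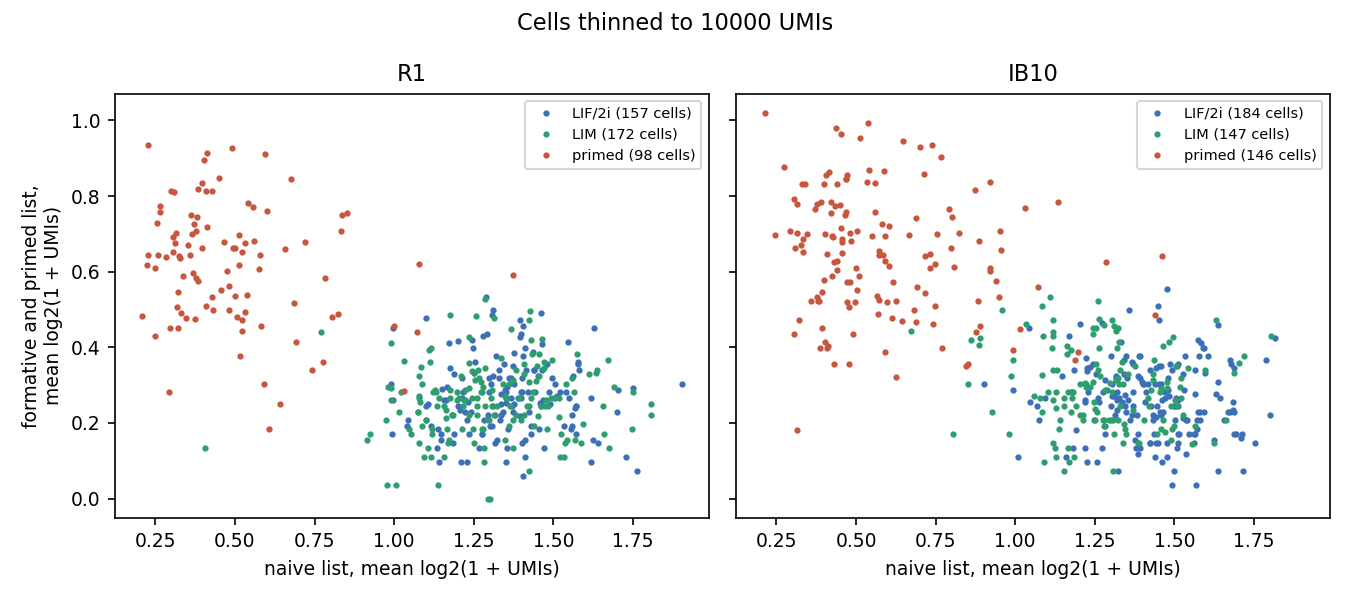
Naive score (horizontal) against formative and primed score (vertical) of single cells thinned to 10000 UMIs, as mean log2(1 + UMIs) per list, with 1 point per cell and 1 panel per line. Rosette_LIM cells overlap LIF_2i cells (medians of 1.28 and of 1.36 to 1.44 on the horizontal axis) and lie apart from primed_4d cells (0.441 and 0.524).

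Otx2 was seen in the same cells as naive genes. At 10000 UMIs, a UMI of Otx2 was found in 21 of 172 R1 rosette_LIM cells (12.2%, exact 95% interval 7.72 to 18.1) and 18 of 147 IB10 cells (12.2%, 7.42 to 18.7). In LIF_2i, which serves as the background, it was found in 1 of 157 (0.637%, 0.016 to 3.50) and 6 of 184 cells (3.26%, 1.21 to 6.96). In primed_4d it was found in 9 of 98 (9.18%, 4.29 to 16.7) and 19 of 146 cells (13.0%, 8.02 to 19.6). Of the rosette_LIM cells, 17 in R1 (9.88%, 5.86 to 15.4) and 15 in IB10 (10.2%, 5.83 to 16.3) had both Otx2 and Klf4, where independent detection gives 9.73% and 9.83%. Cells with both Otx2 and Zfp42, a naive zinc finger gene, made up 12.2% in each line (12.1% and 12.2% if independent). With Esrrb the shares were 9.88% and 12.2% (11.4% and 11.7% if independent), and with Tfcp2l1 9.88% and 8.16% (9.51% and 9.50% if independent). In primed_4d, Otx2 and Klf4 were found together in 0 of 98 R1 cells (exact 95% interval 0 to 3.69%, with 0.75% if independent) and in 3 of 146 IB10 cells (2.05% if independent). Otx2 was found with Zfp42 in 6.12% and 6.85% of primed_4d cells (4.12% and 8.82% if independent), with Esrrb in 6.12% and 4.11% (2.62% and 4.10%) and with Tfcp2l1 in 1.02% and 1.37% (0.843% and 1.78%). Without thinning, over all 188 wells, Otx2 was found in 4.79% and 12.8% of LIF_2i, 29.3% and 25.5% of rosette_LIM and 20.7% and 28.2% of primed_4d wells (R1 and IB10). Zfp42 was found in 171 of 172 R1 and 147 of 147 IB10 rosette_LIM cells and Esrrb in 93.0% and 95.2%, so the shares with them lie near that of Otx2 alone by construction. The intervals cover counting error only.

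Clustering of 946 cells gave 7 clusters that followed the conditions: between 97.2% and 100% of the cells of each library lay in clusters led by their own condition. Clusters 3 and 5 held 76.0% and 23.1% of R1 and 37.9% and 62.1% of IB10 primed_4d cells. They were primed-like, with all 8 markers detected and Pou3f1 and Dnmt3b (cluster 3) and Lef1 (cluster 5) among the 10 leading genes. Their primed markers summed to 1697 and 1039 ppm, against 128 to 178 ppm in the other clusters, and their naive markers to 181 and 694 ppm, against 2408 to 2939 ppm. All 8 naive markers were detected in each of the 7 clusters, so the other 5 were given no name. Of them cluster 6 had 1 naive marker (Tfcp2l1) among its 10 leading genes and clusters 1, 2, 4 and 7 had 0. Rosette_LIM cells lay in clusters 1 (89.4% of R1, 21.3% of IB10 cells) and 4 (7.82% and 77.3%). LIF_2i cells lay in clusters 2 (71.3% of R1, 16.9% of IB10), 6 (18.1% and 52.7%) and 7 (10.6% and 30.4%). None of the markers fixed in advance for 2-cell, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm or fibroblast cells was among the 10 leading genes of a cluster. Tubb3, which is in the neuroectoderm list but not among these markers, stood 9th in cluster 1 (178 ppm against 70.4 ppm in the other clusters). Within LIF_2i and rosette_LIM the clusters went in part with the chromosome 8 share of the cells. In IB10 LIF_2i 93.6% of cluster 2 and 0% of cluster 6 cells had a high share, and in IB10 rosette_LIM 96.6% of cluster 1 and 1.72% of cluster 4 cells. Cluster 7, with 1.79% in IB10 LIF_2i, did not part from cluster 6 by this share. In R1 LIF_2i clusters 2, 6 and 7 had 92.9%, 7.14% and 47.1%, and in R1 rosette_LIM clusters 1 and 4 had 89.6% and 23.1%.

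IB10 was compared with R1 across the conditions to separate line from culture. Mid1, an X-linked ubiquitin ligase gene, was 8.70-fold higher in IB10 (log2 3.12 ± 0.33, edgeR adjusted p = 0.000639, n = 3 libraries per line). Efhc2 (1.77 ± 0.27), the cyclin Ccnd2 (1.68 ± 0.27), Cited4 (1.39 ± 0.26) and Qprt (1.30 ± 0.22) followed, with edgeR adjusted p of 0.00935, 0.0125, 0.0225 and 0.0139. Lower in IB10 were the acute phase gene Saa3 (−3.38 ± 0.55, edgeR adjusted p = 0.0136) and annexin Anxa2 (−1.72 ± 0.20, edgeR adjusted p = 0.00191). The kinase Camk4 (−2.50 ± 0.43), Hoxb2 (−2.48 ± 0.51) and Dcdc2c (−2.17 ± 0.40) were lower too, with edgeR adjusted p of 0.0139, 0.0374 and 0.0203. On log2(CPM + 5), Mid1 differed by 3.32, 1.55 and 3.91 and Anxa2 by −1.05, −1.14 and −1.17 in LIF_2i, rosette_LIM and primed_4d. In the same order Hoxb2 differed by −0.01, −0.23 and −1.74 and Dcdc2c by −0.83, −0.13 and −2.63. Mid1 lies on chromosome X from 169685199 to 170005736, Anxa2 on chromosome 9 from 69453620 to 69491795 and Saa3 on chromosome 7 from 46711998 to 46715700 (GRCm38). Over 12098 genes edgeR called 29 higher and 62 lower in IB10 (0.75%), 13 and 19 by 2-fold or more. Without R1 LIF_2i edgeR called 0 and 0 (891 genes at an unadjusted p under 0.05), and DESeq2 called 15 and 35 with all libraries. So the calls for Mid1, Anxa2 and the other genes above were all lost without R1 LIF_2i. Without IB10 LIF_2i the calls were 4 and 8, without R1 rosette_LIM 150 and 218, and without IB10 rosette_LIM 154 and 225. With no rescaling they were 32 and 31, so that 50.8% rather than 31.9% were higher.

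Of the list members, the naive gene Nr0b1 (0.67 ± 0.10) and the germline gene Sycp3 (0.75 ± 0.16) were higher in IB10, with edgeR adjusted p of 0.009 and 0.0463. The ligand Nodal (−0.58 ± 0.12) and the integrin Itgb1 (−0.48 ± 0.10) were lower, with edgeR adjusted p of 0.0374 and 0.0315. All 4 calls were lost without R1 LIF_2i, and no other list member passed. Camera called 7 lists at the preset correlation, and each had an adjusted p = 0.611 with an estimated correlation. Mitochondrially encoded genes were called higher in IB10 (camera adjusted p = 2.83e-05). Of their 12 members edgeR called 0 (8 at an unadjusted p under 0.05, and 0 by DESeq2 and limma), and 6 when adjusted over the list alone, with mtNd3 at 0.32 and mtAtp6 at 0.30. Glycolysis was called higher (camera adjusted p = 0.0186), with 0 of 14 past edgeR (4 unadjusted, 0 by DESeq2, 1 by limma), 3 adjusted over the list alone and Hk2 at 0.44. DNA methylation was called higher (camera adjusted p = 0.0198), with 0 of 10 past edgeR (1 unadjusted, 0 by DESeq2 and limma), 1 adjusted over the list alone and Tet1 at 0.36. LIF/STAT3 targets were called higher (camera adjusted p = 0.0286), with 0 of 13 past edgeR (2 unadjusted, 0 by DESeq2 and limma), 0 adjusted over the list alone and Pim1 at 0.30. Germline genes were called higher (camera adjusted p = 0.0253), with Sycp3 the 1 of 14 past edgeR and over the list alone. Neuroectoderm was called lower (camera adjusted p = 0.0186), with 0 of 5 past edgeR (3 unadjusted, 0 by DESeq2 and limma), 3 adjusted over the list alone and Nes at −0.89. Nodal/Activin targets were called lower (camera adjusted p = 0.0186), with 1 of 13 past edgeR and 3 adjusted over the list alone. The other 18 lists were not called, with camera adjusted p from 0.0623 to 0.944. Among them the tests pointed up for feeder fibroblast genes (median 0.01, mean −0.05), formative and primed genes (0.05 and −0.01) and S phase (−0.01 and 0.01). With an estimated correlation 1 list had an unadjusted p under 0.05, and fry called 0 lists (2 at an unadjusted p under 0.05). Without either primed_4d library 2 lists were called.

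Genes on chromosome 8 were lower in IB10. Of 62 genes called lower, 29 lay there (46.8%, against 5.49% of genes tested), among them Itgb1. Of the 29 higher genes 0 did (Fisher's exact test, two-sided, p = 1.13e-20 and 0.405). Genes are not independent, so p is too low. The median of 381 chromosome 8 genes differed between IB10 and R1 by −0.25 in LIF_2i, −0.26 in rosette_LIM and −0.31 in primed_4d, while the medians of the 19 other chromosomes lay between −0.04 and 0.10. Single cells fell into a high and a low class by the share of their UMIs from chromosome 8. The high class held 72.6% (exact 95% interval 64.9 to 79.4) of R1 LIF_2i, 83.7% (77.3 to 88.9) of R1 rosette_LIM and 87.8% (79.6 to 93.5) of R1 primed_4d cells. In IB10 it held 16.3% (11.3 to 22.5), 20.4% (14.2 to 27.8) and 22.6% (16.1 to 30.3), with 1 to 2 cells per library within 0.05 of the threshold. Chromosome 6 was high in 14.7%, 15% and 19.9% of IB10 cells and in 1.27%, 0.581% and 0% of R1 cells. Of the IB10 cells high for chromosome 6, 25 of 27, 22 of 22 and 27 of 29 were also high for chromosome 8 (p = 9.65e-24, 7.17e-20 and 2.1e-21 by Fisher's exact test, two-sided). Within cells of high chromosome 8 share, Efhc2 was at −0.25 and Itgb1 at 0.0006 between the lines, and within cells of low share Itgb1 was at 0.06. Both the classes and their thresholds were chosen after the data were seen.

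**Figure D4:**
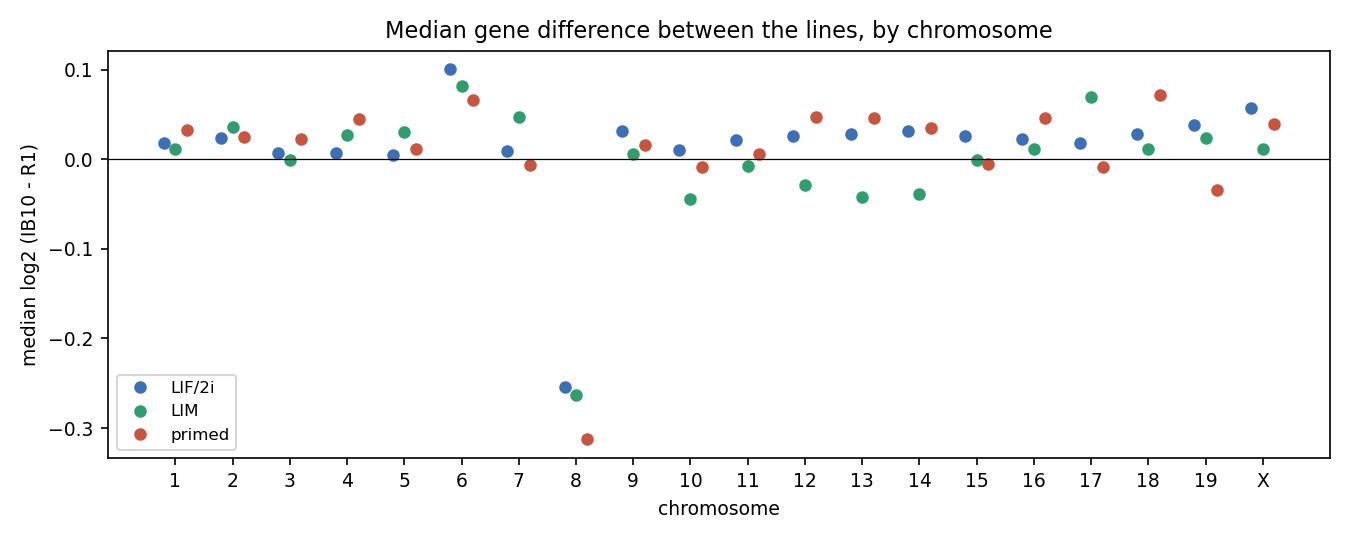
Median IB10 minus R1 difference (log2) of the genes on each chromosome, with 1 point per condition. Chromosome 8 lies at −0.25, −0.26 and −0.31, and all others between −0.04 and 0.10.

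**Figure D5:**
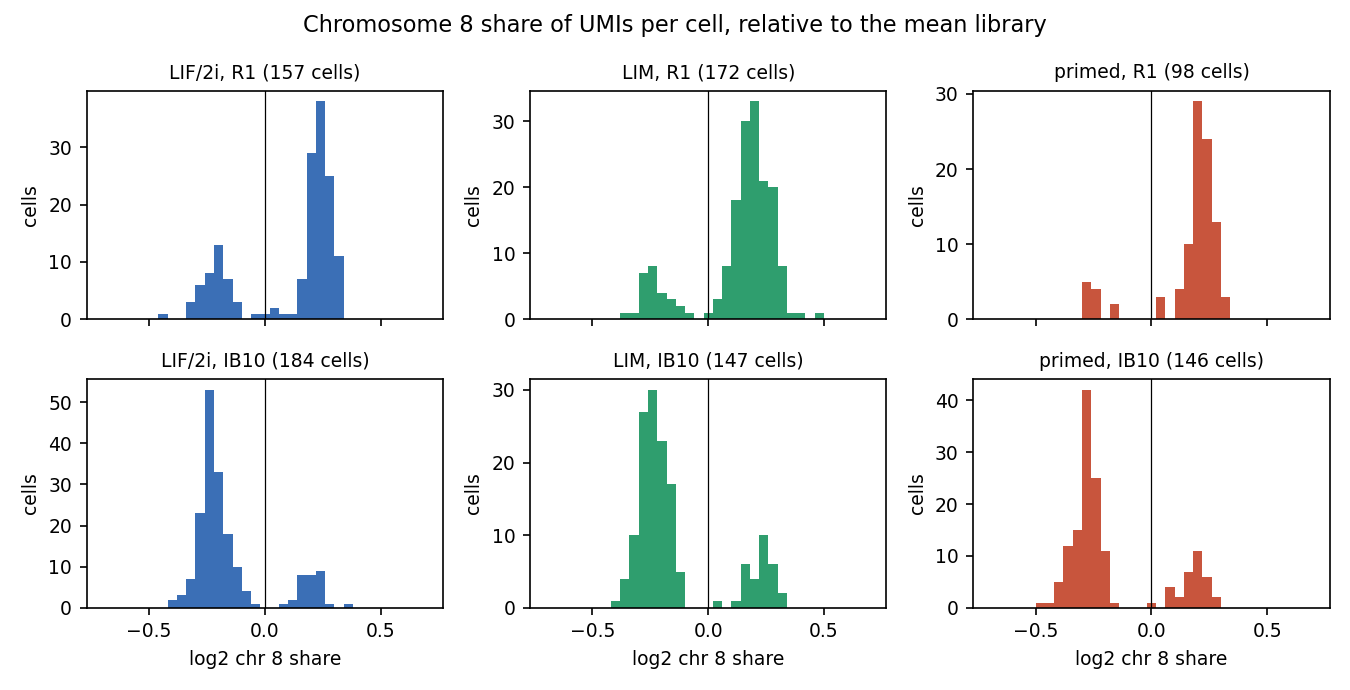
Number of cells (vertical) by the chromosome 8 share of their UMIs (horizontal, log2 against the mean of the 6 libraries), with 1 panel per library and the threshold at 0. Most R1 cells lie above the threshold (72.6% to 87.8%) and most IB10 cells below it (16.3% to 22.6% above).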

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

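The test of shallow reading, the thinned and equal-amount references and the 3 tests on chromosome 8 were chosen after the result was seen, while the tests of the spread between shallow wells and of other splits of the libraries were set down before their results. Spike-in RNA, which no comparison used, gave a signal that differed between libraries. The median well of 6000 UMIs or more held 62.1 (R1) and 72.5 (IB10) gene UMIs per ERCC UMI in LIF_2i, 50.2 and 48.3 in rosette_LIM, and 71.4 and 64.5 in primed_4d. Spike-in amounts per plate are not given in the sources used here, so these ratios carry no test.

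The shallow wells of R1 primed_4d held more naive RNA than the deeper wells of that library (0.545%, Wilson 95% interval 0.501 to 0.593, against 0.323%), with mitochondrial genes at 10.1% of UMIs against 6.29% and a median ERCC share of 39.3% against 1.38%. An unbiased shallow reading of the library's own cells was argued against by 83 other genes, chosen in IB10 as higher in LIF_2i, which took 0.411% (0.369 to 0.455 over resampled wells) against 0.116%, while 66 genes higher in primed_4d took 0.445% against 0.963%. RNA of other cells spread over the wells and a mixture of cells with the LIF_2i and the primed share both stay open as hypotheses. The dispersion of the naive share between shallow wells, 1.74, passed the bound of 1.32 set beforehand for 1 common share, but that bound was too low, since deeper wells of the library thinned to the same depths gave 1.25 to 2.51, an equal amount of LIF_2i RNA per well 0.934 to 1.77 and a mixture 1.55 to 2.64. A bias of shallow wells or damaged RNA stays open, with mitochondrial genes higher in the shallow wells of all 6 libraries, but the 83 genes took 0.142% (0.104 to 0.188) against 0.105% in IB10 primed_4d and a lower share in the shallow wells of the 4 other libraries, and the naive share was higher in R1 rosette_LIM (0.970%, 0.836 to 1.12, against 0.787%), lower in IB10 rosette_LIM (0.611% against 0.733%) and within its interval in IB10 primed_4d (0.377%, 0.326 to 0.435, against 0.396%), R1 LIF_2i (0.755% against 0.766%) and IB10 LIF_2i (0.997%, 0.807 to 1.23, against 0.811%), while cell line and condition stay open and untested.

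Chromosome 8 genes were lower in IB10 than in R1 in each condition. A few abundant genes were argued against: cells sorted by one side of the chromosome differed in the median gene of the other side by at least 0.353 in each library. A line-wide difference in reading these genes was argued against, since within cells classed as high or low by one side of the chromosome IB10 and R1 differed on the other side by at most 0.0858, against −0.22 to −0.30 over all cells. A gain of chromosome 8 in part of the cells stays open as a hypothesis, with a held-out difference of at least 0.355 in R1, where the highest other chromosome reached 0.0769, while in IB10 chromosome 6 reached 0.416. Cells of the high and low class differed by 0.418 to 0.470, under the 0.585 that 3 copies against 2 give, a karyotype of these cells would test the gain, and other ways in which the lines differ biologically stay open and untested.

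Of the 10 splits of the 6 libraries into 3 and 3, only that by line called genes (91). Others had up to 912 at an unadjusted p under 0.05 (edgeR only). Splits without 1 library of each condition per side have less power, as condition is in the model. A share under 0.05 cannot be reached.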

How the results depend on the processing

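limma with equal weight per cell, RLE factors, library totals without TMM, wells of 6000 UMIs or more, leaving out the largest wells, UMIs before the correction, leaving out chromosome 8 genes and the classes of cells by chromosome 8 share were chosen after seeing the data, and the other alternatives before. For genes named by rule no call reversed except those given here. Of 285 results (1 per gene and comparison, called or not) 284 held with RLE and 282 with library totals without TMM. Wells of 6000 UMIs or more kept 283 and UMIs before the correction all. limma kept 197 of 201 tested at 5 ppm, 198 at 1 ppm and 194 at 20 ppm. DESeq2 kept 231 of 269, with no adjusted p for 1173 genes in rosette_LIM against LIF_2i and 5629 in IB10 against R1. A fit without 1 library takes the lone library of that group to vary like the other groups. Taking the same number of cells per library was not run, since all libraries have 188 wells. On simulated counts edgeR found 61% of genes changed by a log2 of 1, not split by abundance. Depth limits the cells that enter the scores, with 98 of 188 R1 primed_4d wells at 10000 UMIs or more.

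In rosette_LIM against LIF_2i (386 rose and 284 fell), 590 and 495 were called with no filter and 167 and 147 at 50 ppm, where more or fewer genes enter. No rescaling gave 149 and 3083 and DESeq2 170 and 109, and limma with equal weight per cell gave 236 rises (8712 genes), where limma at 5 ppm on sums gave 332 (8716 genes); the cause was not tested. Leaving out 1 library gave 28 to 550 rises and 35 to 408 falls, with fewer samples. In primed_4d against LIF_2i (2212 and 2369) the calls were 789 and 890 at 50 ppm, with fewer genes. They were 861 and 6175 with no rescaling, 1343 and 1432 with DESeq2 and 1309 rises by limma with equal weight per cell (1523 by limma at 5 ppm), the cause not tested, and 1036 to 2689 and 1281 to 2788 without 1 library. In rosette_LIM against primed_4d (2299 and 2073) they were 917 and 851 at 50 ppm, and 1223 lower with no rescaling, with the library totals left in. DESeq2 gave 1479 and 1223, the cause not tested, and leaving out 1 library 1720 to 2053 and 1342 to 1847. The share of rises in the 4 comparisons was 57.6%, 48.3%, 52.6% and 31.9%, with library totals without TMM 51.9%, 46.8%, 50.9% and 28.3%, and with limma at 5 ppm 49.2%, 42.8%, 52.6% and 25%.

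In IB10 against R1 (29 higher and 62 lower), no filter gave 128 and 218 and 50 ppm 19 higher, with other numbers of genes. Wells within 3-fold of the median gave 17 and 26, DESeq2 15 and 35, limma at 5 ppm 34 and 102, limma with equal weight per cell 16 and 32, no rescaling 31 lower and leaving out the largest wells 40 lower; the cause was not tested. Without chromosome 8 genes 33 were lower, since these genes then leave the test. Cells of high chromosome 8 share gave 79 and 38, and cells of low share 12 and 13, with fewer cells in each library. Leaving out 1 library gave 0 to 154 and 0 to 225, with fewer samples. Within high-share cells Efhc2 turned to −0.25 and Itgb1 to 0.0006, and within low-share cells Itgb1 turned to 0.058, the cause not tested. With no rescaling Hmmr (−0.023), Cdk1 (−0.070) and Atp5b (−0.032) turned in rosette_LIM and Bub1 (−0.18) and Ndufa1 (−0.11) in primed_4d, each against LIF_2i, since all genes shift by −0.44 and −0.58.

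The cell line was the replicate block. Without it, rosette_LIM against LIF_2i had 162 rises and 119 falls, and 247 of 271 named results held. The other condition comparisons stayed within 1.5 times (1882 and 2054, and 2017 and 1735), and camera called 7, 13 and 11 lists (9, 13 and 11 with the block). Beyond those lists and the 24 calls lost without it, the block changed no other call of the genes and lists named. The cause was not tested.

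Camera called 9 lists in rosette_LIM against LIF_2i. It called 5 at 50 ppm, 5 with no rescaling and 0 with an estimated correlation, fry called 0, and leaving out 1 library gave 7 to 13. Of 13 lists in primed_4d against LIF_2i, the counts were 8 with limma at 5 ppm, 8 at 1 ppm, 8 at 50 ppm, 0 with an estimated correlation and 11 to 13 without 1 library. Of 11 in rosette_LIM against primed_4d, 0 were called with an estimated correlation and 11 to 13 without 1 library. Of 7 in IB10 against R1, limma called 1 at 5 ppm and 1 at 1 ppm, 50 ppm gave 4, wells within 3-fold 4, high-share cells 2 and low-share cells 0. An estimated correlation gave 0, fry 0 and leaving out 1 library 2 to 9. For all of these the cause was not tested, and an estimated correlation leaves fewer degrees of freedom.

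Thinned to 20000 UMIs, Otx2 was found with Klf4 in 20.3% (R1) and 27.8% (IB10) of rosette_LIM cells, with Zfp42 in 21% and 29.4%, with Esrrb in 21% and 29.4% and with Tfcp2l1 in 20.3% and 26.2%. Over all wells without thinning the shares were 27.7% and 25%, 29.3% and 25.5%, 28.7% and 25.5%, and 28.7% and 24.5%. Over wells above the median they were 42.6% and 39.4%, 42.6% and 40.4%, 41.5% and 40.4%, and 42.6% and 39.4%, since deeper cells give more UMIs. With list members found in 10 percent of cells or more, the median naive score was 1.42 and 1.5 in LIF_2i and 1.34 and 1.34 in rosette_LIM, and the formative score 0.450 and 0.439, 0.439 and 0.478, and 1.04 and 1.10 in LIF_2i, rosette_LIM and primed_4d, since fewer genes enter. Clusters numbered 3 at a resolution of 0.5 and 12 at a resolution of 2, by construction. The position of rosette_LIM stayed between 5.01% and 17.1% (R1) and 14.3% and 21.7% (IB10).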

Other observations

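Neuronal, retinoid and imprinted genes were grouped after the data were seen, and the tests given here were chosen then, except that Crabp2, Dll1, Nefm, Tubb3 and Hoxb2 were named by a rule fixed in advance. No test of a neuronal group was made, and of neuronal genes picked by hand some rose and some fell in rosette_LIM against LIF_2i. Those that rose were Crmp1, which acts in axon guidance, by 2.18 ± 0.20 (edgeR adjusted p = 1.35e-05), and the transcription factor Neurod1 by 2.05 ± 0.25 (edgeR adjusted p = 0.000179). The growth cone gene Gap43 (2.27), the peptide gene Calca (2.53) and peripherin Prph (1.72) rose too, with edgeR adjusted p of 0.00128, 1.55e-05 and 0.00941. The neurofilament genes fell, with Nefl at −1.71 (edgeR adjusted p = 4.26e-05) and Nefm at −3.91. In primed_4d against LIF_2i, Crmp1 (3.55), Neurod1 (3.36), Calca (3.73) and Dll1 (5.49) rose, while Tubb3 (−0.74) and Stmn2 (−0.68) fell, as did Mapt, the tau gene, from 24.8 CPM in R1 and 49.1 CPM in IB10 to 2.99 and 0.95 CPM. Of the retinoid genes named here, Crabp2 (3.07), Stra8 (1.24) and Dhrs3 (1.15) rose in rosette_LIM against LIF_2i, with edgeR adjusted p of 1.35e-05, 0.0299 and 0.0255. Hoxb2 (4.78) and Hoxb4 (3.15) rose in primed_4d.

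No test of imprinted or retinoid genes as a group was made either. Of imprinted genes picked by hand in primed_4d against LIF_2i, the maternally expressed RNAs Meg3 (2.31), Rian (2.87) and Mirg (2.15) of the Dlk1-Dio3 region rose, with edgeR adjusted p of 3.08e-09, 3.98e-08 and 2.08e-07. Dlk1 (1.73) rose, and Dio3 of the same region fell by 3.45 (edgeR adjusted p of 0.00131 and 7.01e-05). The cell cycle inhibitor Cdkn1c rose by 4.40, Phlda2 by 2.52 and Peg10 by 2.22, with edgeR adjusted p of 1.08e-08, 3.25e-07 and 3.94e-07, while Plagl1 fell by 3.75 (edgeR adjusted p = 7.07e-09). In rosette_LIM against LIF_2i, Plagl1 fell by 1.94 (edgeR adjusted p = 1.04e-05) and Cdkn1c rose by 1.33 (edgeR adjusted p = 0.0185), and Meg3 (−0.19), Rian (−0.10), Phlda2 (−0.18) and Dio3 (−0.71) did not pass. These values say nothing about which parental copy was read.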
